A study of Homo sapiens with 8 samples.

How the data were processed

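The series holds 8 poly(A) RNA-seq libraries from SK-Hep1 cells, in 4 groups of 2: sorafenib-sensitive cells with control siRNA, sorafenib-resistant cells with control siRNA, resistant cells with COL6A3 siRNA, and resistant cells with COL6A3 siRNA plus recombinant human endotrophin. The labels call the members of a group biological replicates and give a single batch; whether they came from separate cultures or transfections beyond that wording is not given in the sources used here. Cells grew in serum-containing medium, and RNA was extracted with TRIzol. The siRNA sequences, the dose and duration of endotrophin, how resistance was induced, and whether sorafenib was present at harvest are not given in the sources used here. Resistance and the cell population that carries it cannot be separated in this design, since the labels name 1 sensitive and 1 resistant line and no other pair.

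A deposited table gives, for each of 28279 entries, counts per gene from the authors, not normalized, for the 8 libraries. A separate deposited table gives FPKM values, computed by the authors. For each of 10579 genes checked, the counts, the FPKM and the library totals implied the same transcript length in all libraries, within a relative spread of 1e-15, so FPKM is here the count divided by gene length and by the total of the library. The submitters' processing notes name the genome build GRCh38; the aligner, the counting tool, the annotation and the strandedness are not given in the sources used here. The entry without a gene name held 0 counts. Among counts of 1 to 20, 72.8% to 77.6% were even in each library, against 49.6% to 50.9% among counts of at least 500, as when both reads of a pair are counted. Whether that was done is not given in the sources used here, and halved counts were tried as an alternative. Positions of named genes come from a RefSeq gene table of GRCh38, which held 26998 of the 28278 symbols.

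Library totals were 37096702 and 31476743 counts in sensitive control cells, 30461668 and 31569154 in resistant control cells, 31072043 and 35702856 with the siRNA, and 44116043 and 35397934 with siRNA and endotrophin. The libraries detected 15301 to 16594 genes, and the 10 most abundant genes took 3.71% to 4.58% of the counts. Differences between replicates exceeded counting noise: among genes with enough counts, chi-square per degree of freedom was 16.5 to 20.5 within groups, so precision rests on replicate spread and not on depth. Where both libraries of a group were at 0, fold changes are given as at least the ratio to a floor of 3 counts in each library; floors and binomial intervals cover counting error only. If both reads of a pair were counted, a floor of 3 pairs would be 6 counts and each such bound 2-fold lower. Genes with near-identical copies, such as HLA genes, histones and keratins, and genes overlapping others on the opposite strand have uncertain values in tables of this kind.

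Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, leaving 15684, libraries were scaled by TMM (factors 0.981 to 1.02), and a quasi-likelihood model with 1 coefficient per group was fitted to all 8 libraries, with 4 residual degrees of freedom. The common biological coefficient of variation was 0.220 and the prior degrees of freedom were 17.4. The 4 comparisons were resistant control against sensitive control, COL6A3 siRNA against resistant control, siRNA with endotrophin against siRNA alone, and siRNA with endotrophin against resistant control. Tests were 2-sided, p values were adjusted by Benjamini-Hochberg within a comparison, and 0.05 was the threshold. CPM are counts scaled to the library total after TMM. Of the genes called, both libraries of one group lay above both of the other in all but 3, 6, 1 and 0 genes of the 4 comparisons; with 2 libraries against 2, chance alone separates the groups of a gene in 33.3% of cases.

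Before the data were examined, 39 gene lists were fixed. Of these 37 had at least 5 genes tested and were compared with other genes by camera (limma 3.58.1) with a preset correlation of 0.01; camera was repeated with an estimated correlation, and fry gave a self-contained test. The collagen VI list, with 3 genes tested, is reported gene by gene, and the list of mitochondrially encoded genes had no member in the table. The lists cover matrix and adhesion, epithelial and mesenchymal state, signalling, growth factors, drug handling, redox, metabolism, the cell cycle, p53 and apoptosis, protein and amino-acid stress, innate immunity, cell types, ribosomes, histones and RNA interference. For each list the text gives the number of genes that rose and fell with adjustment over all genes tested and after adjustment over the list alone; lists not called are described for resistant against sensitive cells and otherwise only in part. Named genes followed a rule also fixed before: COL6A3, COL6A1, COL6A2 and CD44 always; in each comparison the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 1 and groups that did not overlap; up to 3 called genes per list in order of p, or any member of a list that camera called; and the 5 genes with the largest smaller change in each of the 2 overlaps. Some genes this rule names are not reported here. The mention that 3 kinases were not called was chosen after their values were seen.

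Overlaps between comparisons share libraries, so they were set against independent calls, against 20 simulated data sets without any effect, and against differences taken with the shared group split into its single libraries. The share of the siRNA's effect undone by endotrophin is, for a list, the median change with endotrophin against siRNA alone, with its sign turned, as a percent of the median change with the siRNA. Over all changed genes it is a slope estimated with the libraries of a group kept apart. Bootstrap intervals rest on 1000 draws of genes, not of libraries, so they leave out the spread between replicates. The procedure was tested on simulated data: with 100 genes changed 1.5-fold and 100 changed 2-fold, 60% and 78% were called, and 7 of 145 calls were false. The changed genes were drawn from those above a minimum mean count, so recovery among low-level genes was not tested. The 3′ UTR scan and the sequence corrections used transcripts of GENCODE version 29, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures used matplotlib 3.10.9.

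Alternatives fixed beforehand were DESeq2 1.42.0, RLE scaling, no filter, a filter of at least 50 counts in at least 2 libraries, a fit of the 2 compared groups alone, the replicate number as a block, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with FPKM of at least 1 in at least 2 libraries, and leaving out each library in turn, where the lone library left in a group is assumed to vary like the others. Adding 1 to FPKM shrinks the fold changes of low-level genes. Added after the data were seen were halved counts, leaving out the 2 libraries with the fewest detected genes together, and only genes with a mean of at least 500 counts. All 8 libraries and both kinds of values were used.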

Results

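SK-Hep1 is a human liver cancer line with endothelial features, and sorafenib is a kinase inhibitor used against advanced hepatocellular carcinoma. COL6A3 encodes a chain of collagen VI, a matrix protein whose C-terminal fragment is released as endotrophin. CD44 is the cell-surface receptor for hyaluronan and for osteopontin. The libraries allow 3 questions: how resistant cells differed from sensitive cells, what a COL6A3 siRNA changed in resistant cells, and which of those changes moved back when recombinant human endotrophin was added. Each group held 2 libraries, so every value given as mean ± SD has n = 2. Across genes, which are not independent replicates, Pearson's r of log2 CPM (counts scaled to library size) was 0.958 to 0.972 within groups and 0.921 to 0.967 between groups. Genes said to have risen, fallen or changed passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p threshold of 0.05 over the 15684 genes tested. Fold changes are given as log2 values with their SE.

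COL6A3 mRNA was scarce in sensitive cells and abundant in resistant cells, and the siRNA removed most of it. The gene (gene identifier 1293) lies on chromosome 2 from 237324018 to 237414164 in the GRCh38 annotation. Sensitive control libraries held 18.7 ± 1.39 CPM, resistant control libraries 136 ± 0.857, libraries with the COL6A3 siRNA 43.8 ± 1.61, and libraries with siRNA and endotrophin 68.6 ± 3.82. Resistant cells thus exceeded sensitive cells by a log2 fold change of 2.86 (SE 0.12), with adjusted p = 1.65e-13 in edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. With the siRNA the level fell by 1.63 on the log2 scale (SE 0.11; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.72e-09). With endotrophin added, COL6A3 mRNA was 0.65 (SE 0.11) higher than with siRNA alone, and it stayed at -0.98 (SE 0.11) against the resistant control. The counts are summed over the gene, so they do not separate the part that encodes endotrophin from the rest, and the recombinant protein itself leaves no RNA.

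The partner chains of collagen VI moved the other way. COL6A1 (gene identifier 1291, chromosome 21, 45981770 to 46005048) rose with the siRNA from 35.5 ± 7.85 to 128 ± 10.3 CPM, a log2 fold change of 1.85 (SE 0.13). COL6A2 (gene identifier 1292, chromosome 21, 46098112 to 46132848) rose by 0.90 (SE 0.10). Neither chain was called with endotrophin against siRNA alone. COL6A2 was then at 0.17, or 0.014 and 0.32 without siRNA replicates 1 and 2. Resistant control cells had less COL6A1 than sensitive cells, at -0.56 (SE 0.13), but without resistant control replicate 1 the difference was -0.33 and was not called; COL6A2 did not differ detectably between them. CD44 (gene identifier 960, chromosome 11, 35139171 to 35232402) was an abundant mRNA at 1407 ± 25.1 CPM in resistant and 1395 ± 18.3 in sensitive control cells, with no detectable difference. It rose with the COL6A3 siRNA by 0.35 (SE 0.051). The drop of -0.14 (SE 0.051) with endotrophin was not called by edgeR, though it was by DESeq2 (Benjamini-Hochberg adjusted p = 0.0307), and CD44 stayed above the resistant control by 0.22.

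**Figure D1:**
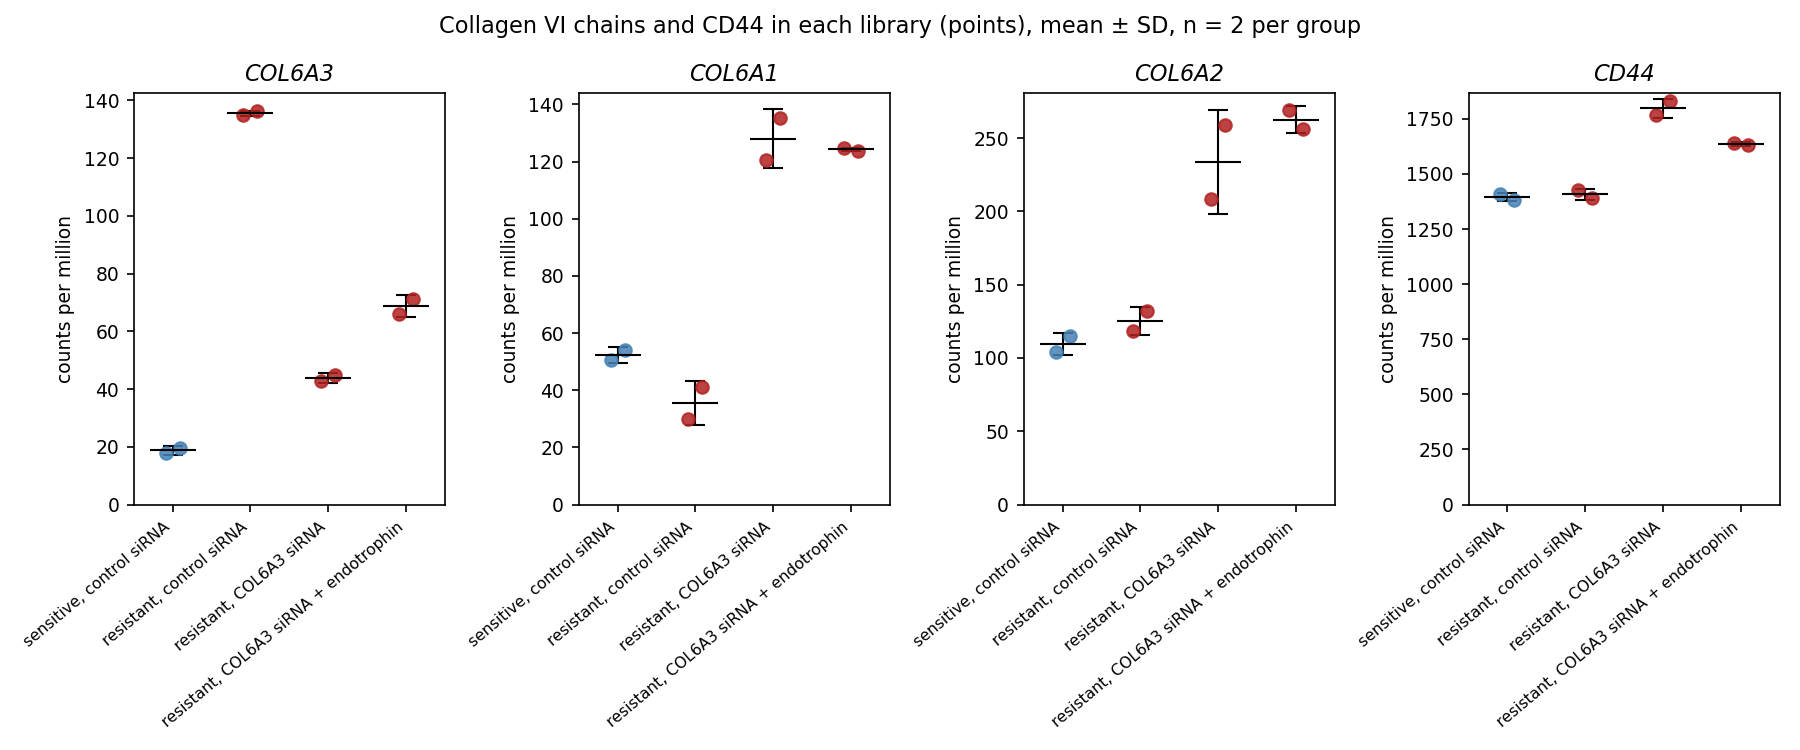
CPM of COL6A3, COL6A1, COL6A2 and CD44 on linear axes from 0, for the 4 groups, with points for the 2 libraries of a group and bars for mean ± SD. COL6A3 falls with the siRNA while COL6A1, COL6A2 and CD44 rise, and with endotrophin COL6A3 moves partway back, as CD44 does by an amount that edgeR did not call.

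Resistant cells carried far less mRNA for the antiviral interferon programme than sensitive cells. Of the 36 interferon-response genes tested, 0 rose, 32 fell and 4 were not called (0 and 33 adjusted over the list alone). OAS2, a sensor of double-stranded RNA, was at -4.62 (SE 0.21); IFIT1, which binds viral RNA, was at -3.57 (SE 0.17); and IFI6 was at -3.17 (SE 0.16). The drop included the ubiquitin-like ISG15 at -3.69. The list median was -2.34 (camera, Benjamini-Hochberg adjusted p = 2.3e-28, or adjusted p = 0.12 with an estimated correlation). Genes that load and present antigen followed: 1 rose, 11 fell and 9 were not called of 21 (1 and 14 adjusted over the list alone), among them HLA-B at -2.47 (SE 0.17), HLA-C at -1.40 (SE 0.13) and the peptide transporter TAP1 at -1.04 (SE 0.14). HLA genes resemble each other closely, so the share of reads assigned to each is uncertain. That list had a median of -0.51 (camera, Benjamini-Hochberg adjusted p = 3.46e-05, or adjusted p = 0.151 with an estimated correlation).

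The matrix and cell-surface profile of resistant cells was rebuilt in both directions. Fibronectin rose from 718 ± 38.3 to 2822 ± 133 CPM (FN1, 1.98, SE 0.055), and so did the fibrillar chains COL5A1 (1.79, SE 0.11) and COL1A1 (1.38) and the laminin-receptor subunit ITGA6 (0.94). TIMP3, an inhibitor of matrix proteases, fell from 215 ± 1.9 to 4.39 ± 1.17 CPM, at -5.61 (SE 0.17). Lysyl oxidase, which crosslinks collagen, fell (LOX, -2.39, SE 0.11), as did SERPINE2 at -2.78, the basement-membrane collagen COL18A1 at -3.39 and LAMB1 at -1.71. KRT19, a keratin of bile-duct and progenitor cells, fell from 207 ± 9.19 to 1.54 ± 0.661 CPM. By list, 3 rose, 6 fell and 7 were not called among 16 other collagens, and 9 rose, 6 fell and 14 were not called among 29 matrix glycoproteins, where the median was -0.11 and camera's direction was up without a call. Of 33 remodelling genes 8 rose, 11 fell and 14 were not called, and of 30 integrin and adhesion genes 7 rose, 7 fell and 16 were not called. Among 16 epithelial genes 0 rose, 7 fell and 9 were not called, including CLDN7 at -3.04. Adjusted over the list alone, 5 and 7, 9 and 6, 8 and 15, 8 and 10, and 2 and 8 genes of these 5 lists rose and fell, and none of the 5 was called by camera. The mesenchymal list was called lower (3 rose, 9 fell and 10 were not called of 22; 4 and 12 adjusted over the list alone, median -0.32; camera, Benjamini-Hochberg adjusted p = 0.0175, or adjusted p = 0.151 with an estimated correlation). That call was lost without sensitive control replicate 1 (median -0.34, adjusted p = 0.113), and the median was -0.21 without resistant control replicate 1.

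Several growth-factor, stress and redox lists held more falls than rises in resistant cells. Of 24 growth-factor ligands and receptors 1 rose, 10 fell and 13 were not called (1 and 13 adjusted over the list alone), among them the receptor gene MET at -0.90 (SE 0.085) and the ERBB ligand NRG1 at -0.98 (SE 0.095). Targets of the YAP and TEAD factors fell in 12 of 26 cases and rose in 1 (2 and 14 adjusted over the list alone), including MYOF at -1.06, IGFBP3 at -1.10 and TGFB2 at -1.44. Of 27 antioxidant and ferroptosis genes 0 rose, 15 fell and 12 were not called (0 and 15 adjusted over the list alone), with NQO1 at -1.43 (SE 0.14), TXNRD1 at -0.66 and the ferroptosis suppressor AIFM2 at -1.86. The p53 targets TP53I3 (-0.90) and TNFRSF10B (-0.56) fell, in a list where 1 rose, 11 fell and 14 were not called of 26 (1 and 11 adjusted over the list alone). Among 24 amino-acid stress genes 3 rose, 9 fell and 12 were not called (3 and 13 adjusted over the list alone), with TRIB3 at -1.47 and the serine-synthesis enzyme PHGDH at -1.19. These 5 lists were called lower by camera, each at a Benjamini-Hochberg adjusted p = 0.00105, with medians of -0.42, -0.37, -0.29, -0.32 and -0.44. With an estimated correlation the adjusted p was 0.151 for growth factors, p53 and amino-acid stress and 0.223 for the other pair. The growth-factor median was -0.64 without resistant control replicate 1.

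HIF1A (-1.15) and the glycolytic enzymes LDHA (-0.66) and PKM (-0.64) fell as well. In the 33 hypoxia and glycolysis genes 1 rose, 11 fell and 21 were not called (2 and 13 adjusted over the list alone, median -0.23; camera, Benjamini-Hochberg adjusted p = 0.0107, or adjusted p = 0.151 with an estimated correlation), but the call was lost without sensitive control replicate 1 (median -0.19, adjusted p = 0.0651), and the median was -0.15 without resistant control replicate 1. Inflammatory genes under NF-κB control included ICAM1 at -2.40, and 1 rose, 11 fell and 18 were not called of 30 (2 and 11 adjusted over the list alone, median -0.47; camera, Benjamini-Hochberg adjusted p = 0.0107, or adjusted p = 0.151 with an estimated correlation). This median was -0.098 without sensitive control replicate 1, where the call was lost (adjusted p = 0.0987), -0.22 without resistant control replicate 1 and -0.30 without resistant control replicate 2. Some DNA-replication genes went the other way: RRM2, a subunit of ribonucleotide reductase, was 0.49 (SE 0.074) higher and the licensing factor CDT1 0.77 (SE 0.12) higher, while 6 rose, 1 fell and 31 were not called of 38 S-phase genes (8 and 2 adjusted over the list alone, median 0.12; camera, Benjamini-Hochberg adjusted p = 0.0292, or adjusted p = 0.151 with an estimated correlation). Without sensitive control replicate 2 this call was lost (median 0.11, adjusted p = 0.0911). In the stellate-cell and fibroblast list 1 rose, 3 fell and 14 were not called of 18 (1 and 4 adjusted over the list alone), with S100A6 at -1.21 (median -1.17; camera, Benjamini-Hochberg adjusted p = 0.0156, or adjusted p = 0.151 with an estimated correlation); the stricter filter on low counts (adjusted p = 0.0527) and FPKM with a pseudocount of 0.1 (adjusted p = 0.0525) lost the call. Endothelial markers were split, 2 and 3 of 13 having risen and fallen (2 and 3 adjusted over the list alone, median -1.14; camera, Benjamini-Hochberg adjusted p = 0.0292, or adjusted p = 0.345 with an estimated correlation), and the call was lost without sensitive control replicate 1 (median -0.63, adjusted p = 0.364), sensitive control replicate 2 (-0.55, adjusted p = 0.226) or resistant control replicate 2 (-1.36, adjusted p = 0.125), while without resistant control replicate 1 the median was -1.73. DESeq2, the stricter filter, FPKM and halved counts ended the endothelial call too. Among genes with a mean of at least 500 counts, a restriction chosen after the data were seen, camera called neither the mesenchymal (Benjamini-Hochberg adjusted p = 0.341) nor the NF-κB (0.106), stellate-cell (0.106) or endothelial list (0.144).

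Genes for the targets and the handling of the drug differed in small numbers. Of 13 sorafenib target kinases 1 rose, 1 fell and 11 were not called: TIE1 was 2.40 higher and KIT was at -0.86. BRAF, ARAF and MAPK14 were not called here or in the other 3 comparisons. Among 17 drug transporters 0 rose, 3 fell and 14 were not called, with ABCC4 at -0.92 (SE 0.11), and among 18 xenobiotic-metabolism genes 0 rose, 6 fell and 12 were not called, with NNMT at -2.76. The pro-survival BCL2L1 was at -1.21 and MCL1 at 0.57, in a list of 28 apoptosis regulators where 2 rose, 7 fell and 19 were not called. Immediate-early and ERK-response genes were split (8 rose, 3 fell and 15 were not called of 26). Counts of genes that rose and fell were 2 and 4 of 18 hyaluronan and CD44 genes, 5 and 4 of 27 TGF-β targets, 1 and 6 of 17 Wnt targets and 3 and 6 of 21 angiogenic factors. For metabolism they were 5 and 5 of 32 sterol and fatty-acid genes and 1 and 3 of 32 oxidative-phosphorylation genes, and 1 and 4 of 22 genes of the unfolded-protein response. They were 3 and 5 of 38 G2/M genes, 3 and 3 of 17 stem-cell markers, 2 and 3 of 47 ribosomal proteins, 0 and 0 of 15 histones and 1 and 0 of 13 RNA-interference genes. Only 8 of 30 hepatocyte markers were high enough to test, of which 1 rose, and none of the 7 macrophage and leukocyte genes tested changed in any of the 4 comparisons. None of these lists was called. When adjusted over the list alone, the numbers that rose and fell were 1 and 1, 0 and 3, 1 and 6, 2 and 7, and 11 and 4 for kinases, transporters, xenobiotic metabolism, apoptosis and immediate-early genes. In the order of the other lists they were 3 and 4, 5 and 4, 2 and 7, 3 and 6, 5 and 5, 1 and 2, 1 and 4, 3 and 5, 3 and 3, 2 and 3, 0 and 0, 0 and 0, and 1 and 0.

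In all, 2480 genes (15.8%) differed between resistant and sensitive control cells: 1022 higher and 1458 lower in resistant cells. Over 2-fold there were 236 higher and 592 lower. Several of the largest differences were near all-or-none. FOXR2, a forkhead factor, was at least 48.4-fold higher in resistant cells, KIAA1324L at least 24.9-fold, VAT1L at least 19.6-fold and FYB1 at least 5.18-fold, all against a floor of 3 counts per library because both sensitive libraries were at 0; a floor of 6 counts would lower each such bound 2-fold. The metalloprotease ADAMTS12 (4.49, SE 0.22) also rose. ARMCX2, TM4SF4, PNPLA4, OLFM1 and the long non-coding RNA UCA1 were at 0 in both resistant control libraries and at least 122, 108, 104, 98.4 and 84.4-fold lower, and the cytoskeletal regulator DPYSL3 fell from 26.7 ± 4.53 to 0.0324 ± 0.0458 CPM. FYB1 was called neither when only the 2 groups were fitted nor on FPKM with either pseudocount, and VAT1L was not called on FPKM with a pseudocount of 1. Without resistant control replicate 1 and sensitive control replicate 2, which had the fewest detected genes, 1538 genes differed.

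**Figure D2:**
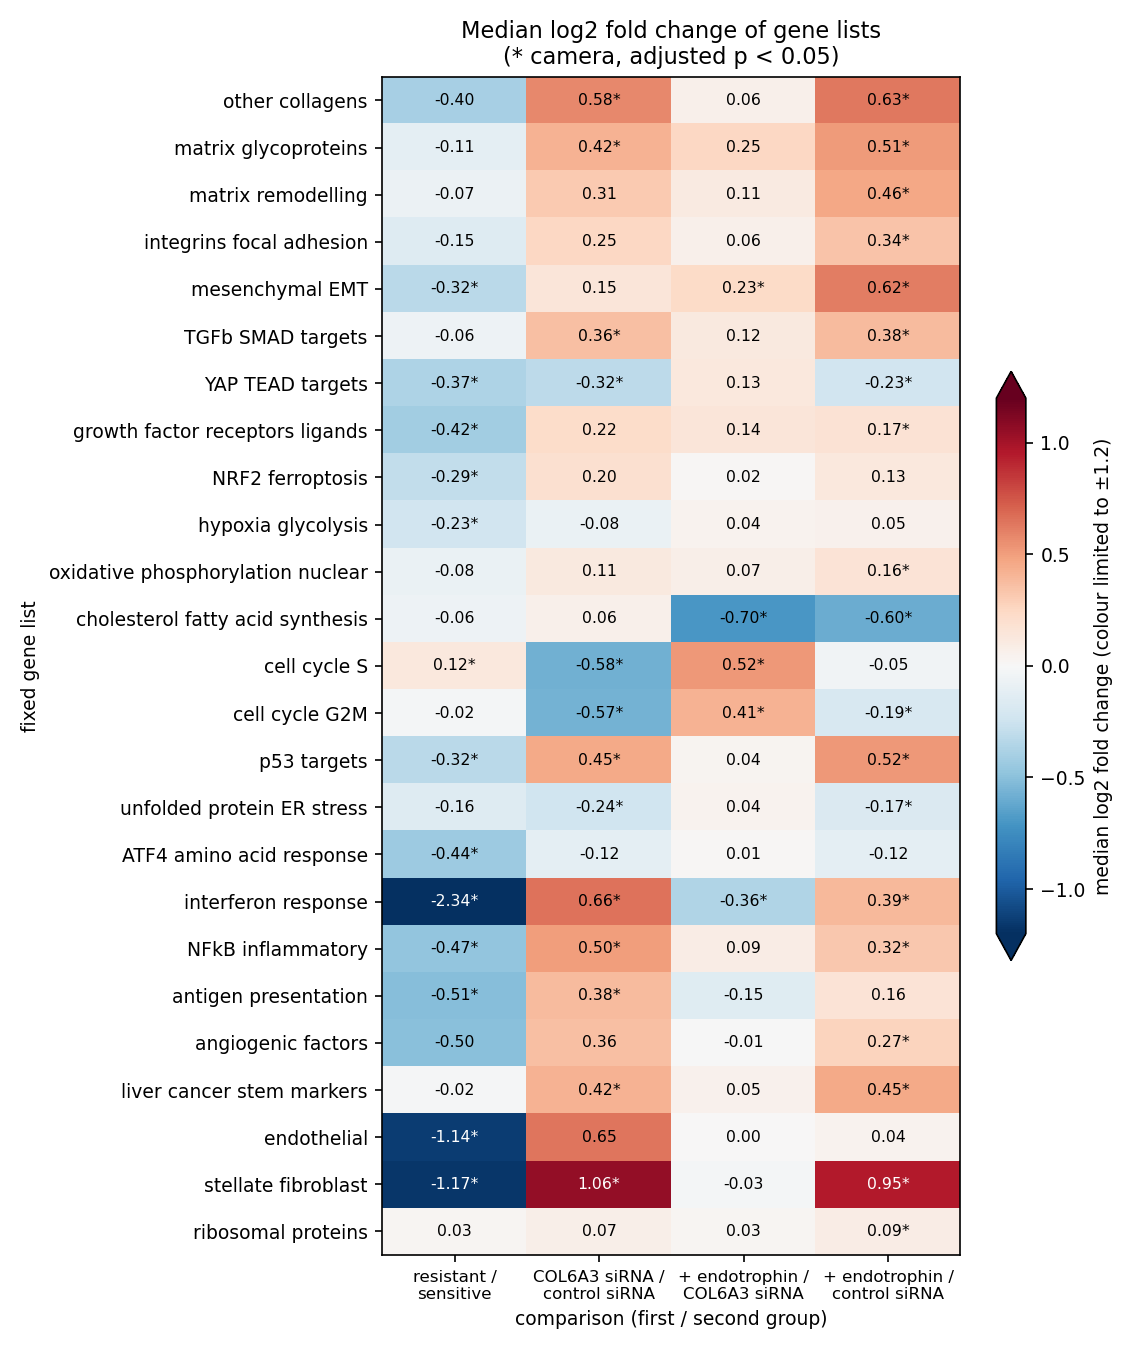
Median log2 fold change (colour and printed value) of the gene lists that camera called in at least 1 of the 4 comparisons, with an asterisk where Benjamini-Hochberg adjusted p passed 0.05. Interferon genes are lowest in resistant against sensitive cells (-2.34), and both cell-cycle lists change sign between the COL6A3 siRNA (-0.58 and -0.57) and endotrophin (0.52 and 0.41).

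With the COL6A3 siRNA the mRNAs of the cell cycle were lower almost throughout. Of 38 S-phase genes 0 rose, 30 fell and 8 were not called (0 and 33 adjusted over the list alone): the origin-licensing factors CDC6 and CDT1 were at -1.42 (SE 0.11) and -1.13 (SE 0.13), and RRM2 was at -0.79 (SE 0.074). Of 38 G2/M genes 0 rose, 36 fell and 2 were not called (0 and 36 adjusted over the list alone), with the anaphase activator CDC20 going from 277 ± 26 to 123 ± 8.49 CPM, the spindle protein PRC1 at -1.01 (SE 0.10) and cyclin B1 (CCNB1) at -0.77 (SE 0.079). The proliferation marker MKI67 fell too, at -0.50 (SE 0.076). Medians were -0.58 for S phase (camera, Benjamini-Hochberg adjusted p = 1.77e-14, or adjusted p = 0.0273 with an estimated correlation) and -0.57 for G2/M (camera, Benjamini-Hochberg adjusted p = 1.46e-17, or adjusted p = 0.0783 with an estimated correlation). Cyclin D1, which drives entry into the cycle, fell (CCND1, -1.35, SE 0.067), and so did MYC at -0.74 (SE 0.082). Targets of p53 rose at the same time: 17 rose, 1 fell and 8 were not called of 26 (18 and 1 adjusted over the list alone, median 0.45; camera, Benjamini-Hochberg adjusted p = 1.02e-05, or adjusted p = 0.0783 with an estimated correlation). TP53INP1 was at 1.92 (SE 0.11), ZMAT3 at 1.32 (SE 0.10) and RRM2B at 1.40 (SE 0.12), while CDKN1A, which encodes the cell-cycle inhibitor p21, was not called (-0.07).

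**Figure D3:**
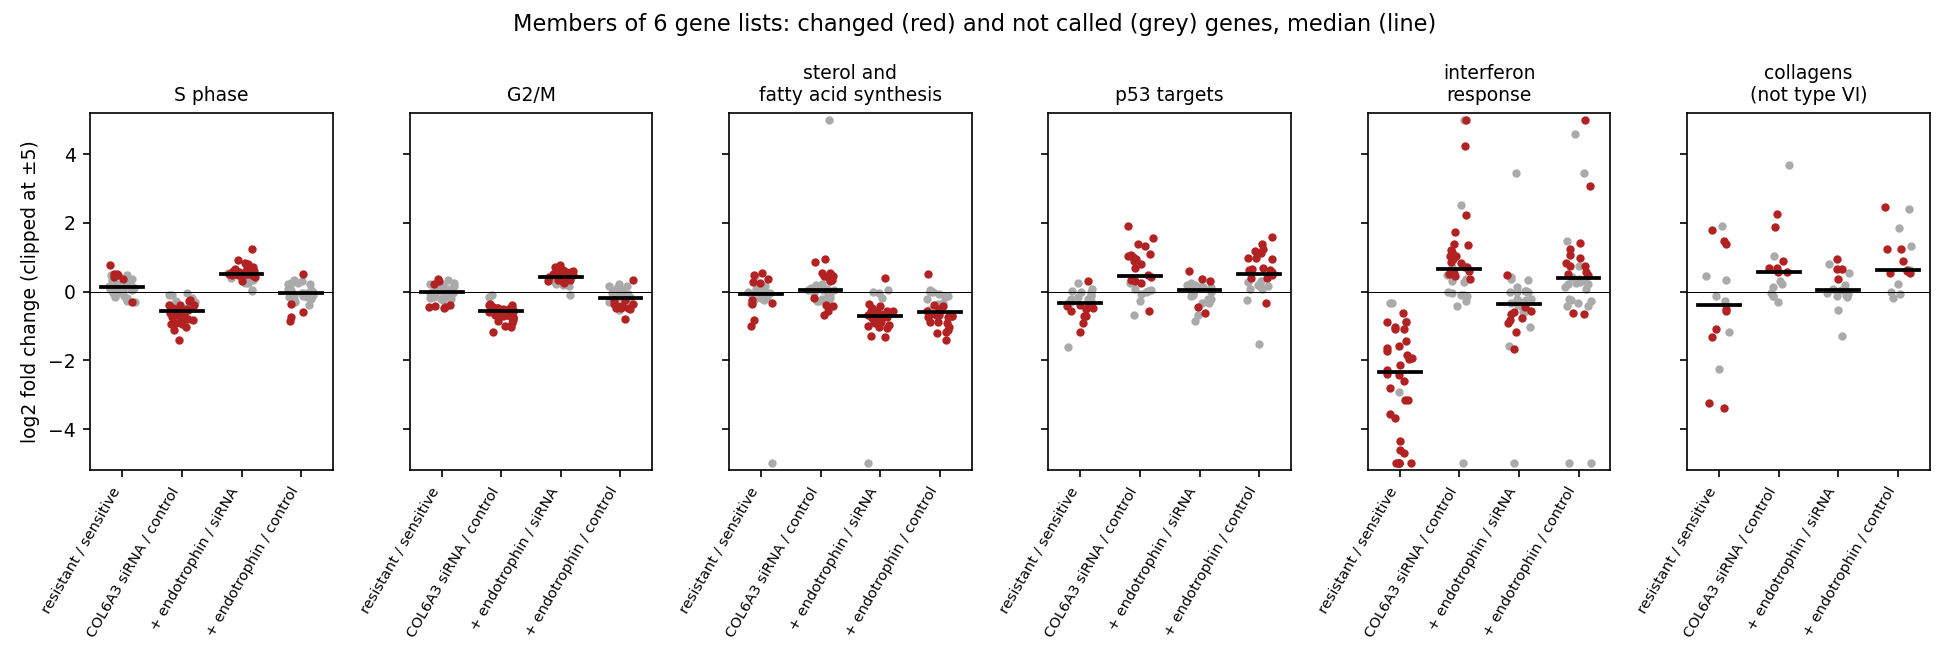
Log2 fold change of every tested member of 6 gene lists in the 4 comparisons, clipped at ±5, with points in red where the gene passed the adjusted p threshold of 0.05, grey where it did not, and lines for medians. Most cell-cycle members fall with the siRNA and rise with endotrophin, while 25 of 32 sterol and fatty-acid genes are called lower with endotrophin against siRNA alone and 5 with the siRNA.

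Some matrix genes rose where COL6A3 fell. Type I collagen COL1A1 went from 28.2 ± 4.14 to 136 ± 10.1 CPM (2.27, SE 0.12), and fibronectin (FN1, 1.04, SE 0.053), fibrillin (FBN1, 2.29, SE 0.16), SPARC (0.83) and COL5A1 (0.88) rose as well. Of 16 other collagens 7 rose, 0 fell and 9 were not called (7 and 0 adjusted over the list alone, median 0.58; camera, Benjamini-Hochberg adjusted p = 0.00495, or adjusted p = 0.286 with an estimated correlation), though the median was 0.31 without siRNA replicate 1. Matrix glycoproteins (10 rose, 3 fell and 16 were not called of 29; 12 and 4 adjusted over the list alone, median 0.42; camera, Benjamini-Hochberg adjusted p = 0.0163, or adjusted p = 0.415 with an estimated correlation) lost the call without resistant control replicate 1 (median 0.39, adjusted p = 0.055) or siRNA replicate 2 (median 0.25, adjusted p = 0.138). Camera did not call remodelling genes (12 rose, 4 fell and 17 were not called of 33; 12 and 6 adjusted over the list alone; Benjamini-Hochberg adjusted p = 0.0723) or integrins (11 rose, 6 fell and 13 were not called of 30; 12 and 6 adjusted over the list alone; adjusted p = 0.125). ITGB8, an integrin subunit that activates latent TGF-β, rose from 12.8 ± 0.544 to 191 ± 8.54 CPM (3.90, SE 0.12), the change with the smallest p in this comparison. TGF-β targets rose more often than they fell (8 rose, 2 fell and 17 were not called of 27; 9 and 2 adjusted over the list alone, median 0.36; camera, Benjamini-Hochberg adjusted p = 0.0142, or adjusted p = 0.195 with an estimated correlation). In the stellate-cell and fibroblast list 8 rose, 0 fell and 10 were not called of 18 (8 and 0 adjusted over the list alone, median 1.06; camera, Benjamini-Hochberg adjusted p = 5.97e-05, or adjusted p = 0.0783 with an estimated correlation), with LOX at 1.00. YAP and TEAD targets fell more often than they rose: 1 rose, 13 fell and 12 were not called of 26 (2 and 16 adjusted over the list alone, median -0.32; camera, Benjamini-Hochberg adjusted p = 9.78e-05, or adjusted p = 0.221 with an estimated correlation), among them the receptor kinase AXL at -1.01 (SE 0.083) and WWC1 at -0.93 (SE 0.11).

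Some interferon-response mRNAs, low in resistant against sensitive cells, were higher with the siRNA than in the resistant control that both comparisons share. Of 36 interferon-response genes 20 rose, 0 fell and 16 were not called (22 and 1 adjusted over the list alone, median 0.66; camera, Benjamini-Hochberg adjusted p = 6.41e-06, or adjusted p = 0.221 with an estimated correlation), including TRIM22 at 2.24 (SE 0.19), OAS2 at 1.73 (SE 0.20) and IFIT3 at 1.04 (SE 0.12). Antigen-presentation genes rose in 7 of 21 cases and fell in 0 (7 and 1 adjusted over the list alone, median 0.38; camera, Benjamini-Hochberg adjusted p = 0.00991, or adjusted p = 0.275 with an estimated correlation), with the immunoproteasome subunit PSMB10 at 1.04, TAPBP at 0.64 and B2M at 0.35. NF-κB genes were called higher (10 rose, 2 fell and 18 were not called of 30; 10 and 2 adjusted over the list alone, median 0.50; camera, Benjamini-Hochberg adjusted p = 0.0261, or adjusted p = 0.213 with an estimated correlation), BIRC3 among them at 1.44. That call was lost without resistant control replicate 1 (median 0.60, adjusted p = 0.0689), resistant control replicate 2 (0.63, adjusted p = 0.0567) or siRNA replicate 1 (0.33, adjusted p = 0.0808). Stem-cell markers were called higher (8 rose, 2 fell and 7 were not called of 17; 8 and 2 adjusted over the list alone, median 0.42; camera, Benjamini-Hochberg adjusted p = 0.035, or adjusted p = 0.221 with an estimated correlation), with SOX4 at 1.38 against ANPEP at -0.89; with no filter on low counts (median 0.51, adjusted p = 0.057), without resistant control replicate 2 (median 0.38, adjusted p = 0.0564) or siRNA replicate 2 (0.45, adjusted p = 0.101) it was not. Some chaperones of the endoplasmic reticulum fell, with HSPA5 at -0.52 and HYOU1 at -0.66 in a list where 1 rose, 9 fell and 12 were not called of 22 (1 and 12 adjusted over the list alone, median -0.24; camera, Benjamini-Hochberg adjusted p = 0.0133, or adjusted p = 0.195 with an estimated correlation). Among genes with a mean of at least 500 counts, camera called neither this list (Benjamini-Hochberg adjusted p = 0.0642) nor TGF-β targets (0.0643), matrix glycoproteins (0.0737) or stem-cell markers (0.23).

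Single genes of metabolism rose or fell with the siRNA. The xenobiotic enzyme CYP1B1 rose from 2.26 ± 1.14 to 44.9 ± 1.09 CPM and ALDH1A3, which makes retinoic acid, rose by 3.05 (SE 0.22). Hexokinase HK2 fell (-1.19, SE 0.11), as did ANGPTL4, an inhibitor of lipoprotein lipase (-1.96, SE 0.18). Xenobiotic-metabolism genes as a list were not called (4 rose, 1 fell and 13 were not called of 18, camera, Benjamini-Hochberg adjusted p = 0.125). Hypoxia and glycolysis genes were not called either (9 rose, 9 fell and 15 were not called of 33, camera, Benjamini-Hochberg adjusted p = 0.967). Adjusted over the list alone, 4 and 1, and 9 and 9 genes of these lists rose and fell. The desaturase SCD rose (0.86, SE 0.049) while fatty-acid synthase fell (FASN, -0.68, SE 0.091), and sterol and fatty-acid genes as a list were not called (10 rose, 5 fell and 17 were not called of 32; 11 and 7 adjusted over the list alone, median 0.056). The siRNA changed 3505 genes (22.3%), 1793 higher and 1712 lower, of which 492 rose and 155 fell over 2-fold. BMF, which encodes a pro-apoptotic BH3 protein, was at 0 in both resistant control libraries and at least 37.3-fold higher with the siRNA, and OLFM1 was at least 6.85-fold higher, a call not made on FPKM with either pseudocount. ELFN1 (6.26), PTPRE (5.04), TMEM217 (4.55) and PLXNB1 (4.39) rested on a few counts in 1 control library. ELFN1 was fitted at 10.1 without resistant control replicate 1, and the other 3 at 9.85, 9.57 and 10.2 without resistant control replicate 2. With those few counts gone, such fitted values are not measured folds. Among falls, CHAC2, which degrades glutathione, was at -2.17 (SE 0.32) and LRRC71 at -2.16 (SE 0.48). The ribosomal RNA precursor RNA45SN2 (-3.53) was at -1.32 and not called without resistant control replicate 2, and poly(A) libraries measure it poorly. FIRRE (-2.29) was lost without either siRNA library (-2.37 and -2.18), and RAET1E (-2.25) without resistant control replicate 1 (-1.99) or siRNA replicate 2 (-1.76). On FPKM RAET1E was called with neither pseudocount, and TMEM217 was not with a pseudocount of 1.

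Cell-cycle mRNAs were higher in silenced cells with recombinant endotrophin than in those without. Whether endotrophin itself caused this is not settled, since weaker siRNA action and a difference between the dishes were not excluded. Of 38 S-phase genes 25 rose, 0 fell and 13 were not called (33 and 0 adjusted over the list alone, median 0.52; camera, Benjamini-Hochberg adjusted p = 8.41e-20, or adjusted p = 0.0147 with an estimated correlation). RRM2 went from 284 ± 14.5 to 536 ± 36.9 CPM (0.91, SE 0.075), the S-phase activator E2F1 was at 1.25 (SE 0.14) and the replicative helicase subunit MCM7 at 0.60 (SE 0.075). Of 38 G2/M genes 27 rose, 0 fell and 11 were not called (34 and 0 adjusted over the list alone, median 0.41; camera, Benjamini-Hochberg adjusted p = 1.41e-17, or adjusted p = 0.0907 with an estimated correlation), with CDC20 at 0.71 (SE 0.095), the mitotic kinase AURKB at 0.79 (SE 0.11) and NUSAP1 at 0.61 (SE 0.091). BIRC5, the apoptosis inhibitor survivin, rose at 0.51. Targets of p53 did not move back: 3 rose, 2 fell and 21 were not called of 26 (3 and 3 adjusted over the list alone), with a median of 0.035, a mean of -0.049 and no camera call (Benjamini-Hochberg adjusted p = 0.984).

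In the same comparison, mRNAs of genes that make sterols and fatty acids were lower. Of 32 such genes 1 rose, 25 fell and 6 were not called (1 and 25 adjusted over the list alone, median -0.70; camera, Benjamini-Hochberg adjusted p = 8.41e-20, or adjusted p = 0.0422 with an estimated correlation). SCD fell from 3651 ± 126 to 1920 ± 65.3 CPM (-0.93, SE 0.049), HMGCS1, which commits acetyl-CoA to the sterol route, fell from 598 ± 16.5 to 246 ± 2.97 (-1.28, SE 0.08), and the citrate lyase ACLY (-0.83, SE 0.055), FDPS (-1.06) and FASN (-0.74) fell with them. ABCA1, which exports cholesterol from the cell, rose at 1.21 (SE 0.16). Mesenchymal genes were called higher (9 rose, 0 fell and 13 were not called of 22; 13 and 2 adjusted over the list alone, median 0.23; camera, Benjamini-Hochberg adjusted p = 0.000176, or adjusted p = 0.0907 with an estimated correlation), among them FSTL1 at 0.83 (SE 0.061) and the actin-binding CALD1 at 0.96 (SE 0.11). Single matrix and protease genes that rose were LOXL2 (0.72), the urokinase PLAU (0.97, SE 0.099) and the type IV collagens COL4A1 (0.67) and COL4A2 (0.66). Camera called neither remodelling genes (5 rose, 2 fell and 26 were not called of 33, Benjamini-Hochberg adjusted p = 0.115) nor matrix glycoproteins (8 rose, 1 fell and 20 were not called of 29, adjusted p = 0.13). Adjusted over the list alone, 5 and 2, and 8 and 2 genes of these lists rose and fell. As lists, other collagens (4 rose, 0 fell and 12 were not called of 16; 5 and 0 adjusted over the list alone) and YAP and TEAD targets (8 rose, 4 fell and 14 were not called of 26; 9 and 5 adjusted over the list alone) were not called by camera on the edgeR fit, though other collagens were on that of DESeq2 (median 0.13, Benjamini-Hochberg adjusted p = 0.0177). IGFBP3, a binding protein for insulin-like growth factors, rose from 144 ± 3.93 to 540.1 ± 24.9 CPM (1.90, SE 0.083), the change with the smallest p. Osteopontin, a CD44 ligand, fell (SPP1, -0.98, SE 0.082). Interferon-response genes fell more often than they rose (1 rose, 9 fell and 26 were not called of 36; 2 and 13 adjusted over the list alone, median -0.36; camera, Benjamini-Hochberg adjusted p = 0.000176, or adjusted p = 0.442 with an estimated correlation), with STAT2 at -0.91 and PARP14 at -0.65; the median was -0.24 without endotrophin replicate 2.

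Endotrophin changed 1218 genes (7.77%), 691 higher and 527 lower, with 41 rises and 65 falls over 2-fold. The count was 703 without siRNA replicate 1, 772 without endotrophin replicate 1 and 651 without endotrophin replicate 2, and limma called 683 on FPKM with a pseudocount of 1 and 636 with 0.1. The 6 largest rises included ANGPTL4, from 13.9 ± 2.71 to 67.8 ± 9.2 CPM (2.28, SE 0.18), the G-protein regulator RGS4 (2.06, SE 0.14), the keratin KRT81 (1.99, SE 0.22) and the secreted CRISPLD2 (2.16, SE 0.37). The immediate-early factor FOSB (2.43, SE 0.52) was not called on FPKM with a pseudocount of 0.1, and IGFBP5 (2.59, SE 0.52) was called neither on FPKM nor by DESeq2 (Benjamini-Hochberg adjusted p = 0.055). EGR1, of the same class as FOSB, rose at 1.49 (SE 0.25). The largest falls within the naming rule, which asks for an average log2 CPM of at least 1 and groups that did not overlap, were less firm. MOCS1, at 0 in both endotrophin libraries, was at least 3.07-fold lower, and DESeq2 gave it no adjusted p. Its call was lost on FPKM, with halved counts and without endotrophin replicate 1 (-6.00 against a fitted -6.05). ENPP5 (-1.96) was lost without siRNA replicate 1 (-1.81) or endotrophin replicate 2 (-1.54), and GDPD1 (-1.96) without endotrophin replicate 1 (-1.56). CLEC2B (-1.93) was lost without siRNA replicate 1 (-1.73) or endotrophin replicate 1 (-1.54), and heparanase (HPSE, -1.79) without siRNA replicate 2 (-1.68) or endotrophin replicate 1 (-1.55). LOC105377267 (-1.83) was lost without siRNA replicate 1 (-1.62), endotrophin replicate 1 (-1.91) or endotrophin replicate 2 (-1.75). ENPP5, GDPD1 and HPSE were not called on FPKM with either pseudocount, nor was LOC105377267 with 0.1.

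Set against the resistant control, cells with siRNA and endotrophin together had near-control levels of S-phase mRNAs. Many sterol and fatty-acid mRNAs were lower, and several matrix mRNAs were higher. Of 38 S-phase genes 1 rose, 4 fell and 33 were not called (1 and 2 adjusted over the list alone), with a median of -0.046 and no call, while G2/M genes stayed lower (1 rose, 12 fell and 25 were not called of 38; 1 and 16 adjusted over the list alone, median -0.19; camera, Benjamini-Hochberg adjusted p = 0.00116, or adjusted p = 0.297 with an estimated correlation). CCND1 remained at -1.43 (SE 0.067) and CDC6 at -0.87 (SE 0.11). Sterol and fatty-acid genes were below the control (1 rose, 20 fell and 11 were not called of 32; 1 and 23 adjusted over the list alone, median -0.60; camera, Benjamini-Hochberg adjusted p = 1.81e-11, or adjusted p = 0.0844 with an estimated correlation): FASN was at -1.42 (SE 0.092), ACLY at -1.02 (SE 0.055) and the sterol cyclase LSS at -1.13 (SE 0.08), whereas SCD no longer differed detectably (-0.068). COL1A1 (2.46, SE 0.12), FN1 (1.29, SE 0.054), FBN1 (2.17) and ITGB8 (4.10, SE 0.12) were still raised. The p53 targets TP53INP1 (1.59), ZMAT3 (1.23) and RRM2B (1.38) stayed up as well (16 rose, 1 fell and 9 were not called of 26; 17 and 1 adjusted over the list alone, median 0.52; camera, Benjamini-Hochberg adjusted p = 5.13e-07, or adjusted p = 0.0844 with an estimated correlation). CYP1B1 (4.64) stayed up too, and HMOX1 (1.29) and the inflammatory ICAM1 (2.30) were above the control. IGFBP3 (1.62, SE 0.082) was above the control as well, but rose only when endotrophin was added.

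Camera called 19 lists in this comparison, and none kept its call with an estimated correlation. Of matrix and cell-state lists, those called higher were other collagens (8 and 0 of 16 rose and fell, median 0.63; adjusted p = 6.6e-05), matrix glycoproteins (11 and 2 of 29; 0.51; adjusted p = 0.000351), remodelling genes (14 and 3 of 33; 0.46; adjusted p = 8.25e-05) and mesenchymal genes (12 and 2 of 22; 0.62; adjusted p = 0.000351), all by camera with Benjamini-Hochberg adjustment. By the same test integrins (10 and 3 of 30, median 0.34, adjusted p = 0.0072), TGF-β targets (12 and 2 of 27, 0.38, adjusted p = 0.0095), stellate-cell and fibroblast genes (6 and 0 of 18, 0.95, adjusted p = 9.26e-05) and stem-cell markers (7 and 2 of 17, 0.45, adjusted p = 0.00975) were higher. In the order given, 9 and 0, 15 and 2, 18 and 3, 14 and 2, 12 and 4, 14 and 4, 7 and 0, and 7 and 2 genes rose and fell when adjusted over the list alone. The median of other collagens was 1.01 without resistant control replicate 2, and that of stem-cell markers was 0.69, 0.26 and 0.27 without resistant control replicates 1 and 2 and endotrophin replicate 2, with the calls kept. Among genes with a mean of at least 500 counts, stem-cell markers were not called (median 0.21; camera, Benjamini-Hochberg adjusted p = 0.347).

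Of the remaining lists, growth factors (8 and 1 of 24 rose and fell, median 0.17, adjusted p = 0.00902), interferon-response genes (12 and 2 of 36, 0.39, or 0.33 with genes at 0 set to their bound, adjusted p = 0.0103) and NF-κB genes (9 and 2 of 30, 0.32, or 0.12 at the bound, adjusted p = 0.043) were called higher by camera after Benjamini-Hochberg adjustment. YAP and TEAD targets (2 and 11 of 26, -0.23, adjusted p = 0.0139) and the unfolded-protein response (0 and 6 of 22, -0.17, adjusted p = 0.00852) were called lower by the same test with Benjamini-Hochberg adjustment. Oxidative phosphorylation (3 and 0 of 32, 0.16), angiogenic factors (6 and 1 of 21, 0.27) and ribosomal proteins (10 and 2 of 47, 0.089) were called higher by small medians, with adjusted p = 0.0302, 0.0424 and 0.0435 by camera after Benjamini-Hochberg adjustment. Adjusted over the list alone, 10 and 1, 12 and 5, 9 and 2, 3 and 13, 0 and 6, 2 and 0, 6 and 1, and 10 and 2 genes of these lists rose and fell. Oxidative phosphorylation lost its call without resistant control replicate 1 (median 0.13) or endotrophin replicate 2 (0.13), and YAP and TEAD targets without endotrophin replicate 2 (-0.18). NF-κB genes lost it without resistant control replicate 1 (0.50) or 2 (0.85), and their median was 0.50 to 0.51 without either sensitive or either siRNA library. Angiogenic factors lost it without sensitive control replicate 1 (0.26) or 2 (0.26), resistant control replicate 2 (0.30), or endotrophin replicate 1 (0.24) or 2 (0.31). Ribosomal proteins lost it without sensitive control replicate 1 (0.091) or 2 (0.091), resistant control replicate 1 (0.064) or endotrophin replicate 2 (0.049). The stricter filter on low counts and FPKM with either pseudocount also ended the calls of angiogenic factors and ribosomal proteins, and halved counts those of NF-κB genes and angiogenic factors. Calls were kept where the growth-factor median was 0.30 without resistant control replicate 2 and 0.40 without endotrophin replicate 1, and where the interferon median was 0.16 and 0.23 without endotrophin replicates 1 and 2.

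The comparison changed 2981 genes (19.0%), 1581 higher and 1400 lower, with 424 rises and 173 falls over 2-fold; without endotrophin replicate 2 the count was 1972. BMF, OLFM1 and PNPLA4 were at least 30.2, 14.1 and 3.69-fold higher than the resistant control, where both libraries were at 0, but PNPLA4 was not called by DESeq2 or when only the 2 groups were fitted, nor OLFM1 or PNPLA4 on FPKM. PTPRE (5.01) and TMEM217 (5.02) were fitted at 9.81 and 10.0 without resistant control replicate 2, and ELFN1 (6.94) at 10.8 without resistant control replicate 1. Here too the few control counts are gone, so these are not measured folds. MOCS1 was at least 10.6-fold lower, a call not made on FPKM. GDPD1 (-2.42, SE 0.48) and FAM117A (-2.23, SE 0.30) fell. TMCC1-AS1 (-2.36) was not called on FPKM. ZNF253 (-2.37) was lost without endotrophin replicate 1 (-2.42) or 2 (-2.31), and MYO16 (-2.12) without resistant control replicate 1 (-1.81), endotrophin replicate 1 (-1.93) or 2 (-2.33), or when only the 2 groups were fitted.

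The COL6A3 siRNA moved many resistance-linked genes toward the sensitive state. Of the 2480 genes that differed between resistant and sensitive cells, 805 (32.5%) changed in the opposite direction with the siRNA, 534 of them low in resistant cells and raised by the siRNA and 271 high and lowered. Independent calls would give 278 opposite and 276 in the same direction, where 254 were observed. Both comparisons use the same resistant control libraries, so noise in those libraries alone makes opposite changes. The covariance of the log2 differences across genes was -0.355. In data simulated without any effect it was -0.163, with the control libraries shared in the same way. With separate control libraries on each side, which leaves out their shared noise, the covariance in the real data was -0.116. That split was not simulated, so -0.116 cannot be set against -0.163. At most 1 gene was turned back in the 20 simulated draws, but these averaged only 0.433 calls per comparison. They thus cannot tell how many of the 805 opposite calls came from noise in the shared control libraries. TIMP3 (-5.61, then 1.83), LOX (-2.39, then 1.00) and OAS2 (-4.62, then 1.73) were lower in resistant cells and rose with the siRNA, while CDT1 (0.77, then -1.13) and ITGA6 (0.94, then -0.90) were higher and fell. Ranked by the smaller of their 2 fitted changes, BMF, IRF5, TPD52L1, LYNX1 and PADI2 came first among the genes turned back. All 5 were at 0 in both resistant control libraries, at least 23.7, 17.8, 12.6, 20.1 and 24.4-fold lower there than in sensitive cells, and at least 37.3, 12.7, 13.8, 12 and 11.5-fold higher with the siRNA. PADI2 was not called in the second step without siRNA replicate 1 (5.58 against a fitted 8.26). FN1 and COL1A1 were among genes that rose in both steps, so the siRNA carried them further from the sensitive state.

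Part of the siRNA's changes moved back when endotrophin was added. No group had control siRNA with endotrophin, so a response to endotrophin that does not depend on the siRNA would look the same. Changes called undone here are those that moved back, whatever the reason. Of the 3505 genes the siRNA changed, 635 (18.1%) moved back with endotrophin, 392 after a fall and 243 after a rise. Independent calls would give 136, and 97 genes were pushed further where 137 would be. The count was 338 without siRNA replicate 1, 409 without endotrophin replicate 1, 352 without endotrophin replicate 2, and 356 and 330 on FPKM with pseudocounts of 1 and 0.1. Across genes the covariance was -0.207, against -0.160 in data simulated without effect, both with shared siRNA libraries. With the shared libraries split it was -0.0634 in the real data, a value that was not simulated and cannot be set against -0.160. In the 20 draws without effect at most 1 gene was turned back, but these draws averaged only 0.433 calls per comparison. They cannot show how many of the 635 came from noise in the shared siRNA libraries, and that share is not known. Of the 635 genes, 498 no longer differed detectably from the resistant control, while 1907 of the 3505 were still called in the siRNA's direction. The median shift was undone by 90.4% in S-phase and 73.2% in G2/M genes and by 55.6% in interferon-response genes, of which camera called only S phase with an estimated correlation in these comparisons. Leaving out a library gave 83.2% to 98.4% for S phase and 69.9% to 76.4% for G2/M; for interferon-response genes it gave 43.4% without endotrophin replicate 2 and 74.4% without endotrophin replicate 1. In p53 targets and other collagens at most 2.28% of the median shift was undone with any 1 library left out. Over all 3504 changed genes except COL6A3 the share undone was 20.96% (95% bootstrap interval over genes 18.3% to 23.8%). The interval leaves out the spread between replicates, and the genes were chosen with the same siRNA libraries. COL6A3 itself recovered 39.7% of its loss. Ranked by the smaller of the 2 fitted changes, the largest 2-step reversals were ANGPTL4 (-1.96, then 2.28), GPNMB, OLFML2B, LOC105377267 and KLHDC7A. OLFML2B (2.62, then -1.63) was not called in the second step on FPKM with a pseudocount of 0.1, nor without siRNA replicate 1 (-1.46), endotrophin replicate 1 (-1.53) or endotrophin replicate 2 (-1.72). LOC105377267 (2.12, then -1.83) lost its second call without the same libraries (-1.62, -1.91 and -1.75). GPNMB fell at least 31.8-fold to 0 with endotrophin, a change for which DESeq2 gave no adjusted p. Its rise with the siRNA (5.19) was fitted at 9.44 without resistant control replicate 2, and without siRNA replicate 1 it was 4.96 and not called. KLHDC7A had counts in siRNA replicate 2 alone among the 6 resistant libraries, and without it both differences are 0.

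**Figure D4:**
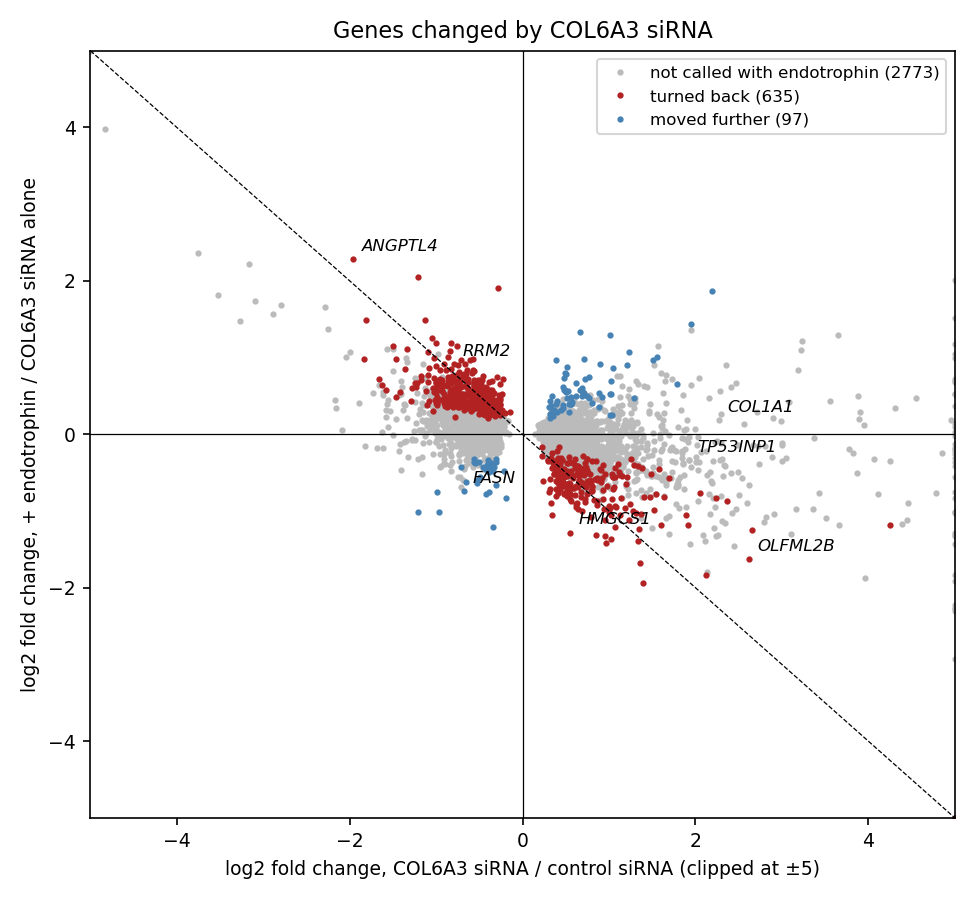
Each gene changed by the COL6A3 siRNA, with its log2 fold change for siRNA against control on the x axis and for added endotrophin against siRNA alone on the y axis, both clipped at ±5 and with a dashed line for full reversal. Red points are the 635 genes turned back, blue the 97 moved further and grey the 2773 not called with endotrophin; most grey points lie near 0 on the y axis.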

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

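Halved counts, leaving out the 2 libraries with the fewest detected genes together, and the restriction to genes with a mean of at least 500 counts were chosen after the data were seen; the other alternatives were not. COL6A3 fell with the siRNA under all 19 alternatives, by a log2 fold change between -1.65 and -1.41 (-1.65 to -1.58 leaving out a library). Genes in the opposite direction in resistance and with the siRNA numbered 556 to 923 under all 19 (582 to 814 leaving out a library). Of the tests of named genes under an alternative, 7942 kept direction and side of the threshold, 294 lost the call, 1 gained it and 5 changed direction; for named lists the numbers were 991, 112, 1 and 9. Leaving out each library in turn gave 1773 to 2655 genes for resistant against sensitive cells, 2469 to 4019 for the siRNA, 651 to 1637 for endotrophin against siRNA alone and 1972 to 3513 for endotrophin against the control. Genes turned back by endotrophin then numbered 338 to 847, and lists called for endotrophin against siRNA alone 5 to 9. Each setting of this kind leaves fewer samples and 3 residual degrees of freedom.

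On FPKM, limma called 683 (pseudocount 1) and 636 (0.1) genes for endotrophin against siRNA alone and found 356 and 330 turned back, against 1218 and 635. The cause was not tested. Without the 2 libraries with the fewest detected genes, 1538 genes differed between resistant and sensitive cells, with fewer samples on both sides, and the CD44 difference was -0.018 in place of 0.013. With the replicate number as a block, 2606, 3618, 1368 and 3113 genes were called in the 4 comparisons, while the block ended the calls of stem-cell markers with the siRNA (median 0.42) and of NF-κB genes (0.32) and ribosomal proteins (0.089) with endotrophin against the control, and replicate differences correlated by only -0.027 to 0.036 between groups across genes, which gives no sign that equal numbers pair libraries. DESeq2's fit gave 11 called lists for endotrophin against siRNA alone, where edgeR's gave 5; the cause was not tested. With an estimated correlation camera called 0, 1, 2 and 0 lists in the 4 comparisons in place of 13, 13, 5 and 19, since it allows for genes of a list varying together. Fry, which does not compare a list with other genes, called 23 lists for resistant against sensitive cells, 23 for the siRNA, 12 for endotrophin against siRNA alone and 22 for endotrophin against the control. With the shared libraries split, the covariance across genes was -0.116 for resistance and siRNA and -0.0634 for siRNA and endotrophin, as noise in libraries that both sides share is then left out.

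Some list medians moved by over 1.5 times with the call kept. For resistant against sensitive cells NF-κB genes were at -0.24 with DESeq2 and -0.25 with no filter, stellate-cell genes at -0.46 on FPKM with a pseudocount of 1, and amino-acid stress genes at -0.27 among genes with a mean of at least 500 counts. For the siRNA other collagens were at 0.24 and 0.30 on FPKM with pseudocounts of 1 and 0.1, stellate-cell genes at 0.62 and 0.65 there and 0.67 among genes with a mean of at least 500 counts, and NF-κB genes at 0.26 with a pseudocount of 1. For endotrophin against the control the values with a pseudocount of 1 were 0.30 for matrix glycoproteins, 0.21 for interferon, 0.11 for NF-κB (0.18 with 0.1) and 0.62 for stellate-cell genes. Among genes with a mean of at least 500 counts mesenchymal genes were then at 0.34 and NF-κB genes at 0.74, and without the 2 libraries with the fewest detected genes TGF-β targets were at 0.25 and stem-cell markers at 0.69. The causes were not tested, beyond the shrinkage that adding 1 to FPKM gives low-level genes.

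Results that changed direction were all near 0 or rested on 1 library. Leaving out a library moved COL6A1 with endotrophin between -0.13 and 0.031, CDKN1A with the siRNA between -0.19 and 0.068, and KLHDC7A between 0 and 7.55 with the siRNA and between -7.55 and 0 with endotrophin. For p53 targets with endotrophin against siRNA alone, camera's direction turned with no filter (median 0.026), with the replicate block (0.036), on FPKM (0.0055 and 0.0078), and without either resistant control library, siRNA replicate 1 or endotrophin replicate 2, the medians leaving out a library being -0.010 to 0.053. Fry's direction was down on the fit where camera's was up (median 0.035), and none was called. The cause was not tested. Where a group is at 0, only the bounds above hold. Among 100 genes changed 1.5-fold in simulated data 60% were called, but low-level genes were not among those changed there.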

Other observations

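The tests of weaker siRNA action, of direct seed repression of cell-cycle genes, of seed words outside Alu-like sequence, of words whose carriers rose with endotrophin and of low-level genes missed in the resistant control were chosen after the result was seen; the tests of GC content or length and of seed matches among all falls were not.

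Some changes of single genes are not described above. TBX3, a T-box factor, was 1.72 (SE 0.087) higher in resistant than in sensitive cells, while DKK1, a secreted Wnt inhibitor, was at -0.97 (SE 0.078) and the BMP antagonist GREM1 at -3.01 (SE 0.27). DKK1 rose with the COL6A3 siRNA (1.01, SE 0.078) and stood at 1.26 (SE 0.078) with endotrophin against the control. The metallothionein MT1X was at 2.41 (SE 0.31) with the siRNA and 3.03 (SE 0.31) with siRNA and endotrophin, though its family shares much sequence. The sorafenib target FGFR1 rose with the siRNA (0.53, SE 0.099). The amino-acid transporter SLC7A5 was at 0.80 (SE 0.074) with the siRNA and 1.21 (SE 0.074) once endotrophin was present.

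Many mRNAs fell with the COL6A3 siRNA, and some of this may be an off-target effect of the siRNA. Seed-match words, the 7 bases of a 3′ UTR that the siRNA's 5′ end can pair with, were scanned over 9795 words of COL6A3 mRNA: carriers of 128 words lay lower in siRNA against control and of 71 in siRNA with endotrophin against control, past a Bonferroni threshold, and of 0 words in the other 2 comparisons, though carriers of 7 words lay higher with endotrophin against siRNA alone, the lowest with the siRNA being GGTGGCA, which, like GTCCTGA, occurs in 8 of 14 annotated transcripts of the gene. Outside genes with Alu words its 644 carriers among 5815 genes shifted by -0.17 with the siRNA and by -0.16 with endotrophin as well, against 0.0050 and 0.011 in the comparisons with the same siRNA on both sides, and its reverse complement by -0.032 among all genes. A linear model over the 5815 genes gave the shift with the siRNA a Bonferroni adjusted p = 6.05e-17. That p and the counts of words past the threshold treat genes as independent and leave out the spread between replicates. The siRNA sequence is unknown here, so which of the 128 words match it, if any, is unknown too. A seed effect on these carriers would give such a shift. As a source of all 1514 falls among 8509 genes it is not settled: falls among carriers of GGTGGCA beyond the number that 3′ UTR length and GC content predict come to 11.3% of them, the largest excess for a word past the threshold, with its carriers making up 25.2% of genes that fell, 13.6% of those that rose and 17.8% of those not called.

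Cell-cycle genes fell with the COL6A3 siRNA and rose when endotrophin was added. If the siRNA had simply acted less in the endotrophin cultures, genes carrying a candidate seed-match word, GGTGGCA, should have recovered as far as the cell-cycle genes did. Their shift was undone by 4.25% (95% bootstrap interval over genes -6.91% to 15.3%), against 90.4% (80.2% to 109%) for S-phase and 73.2% (57.2% to 85.9%) for G2/M genes. These intervals leave out the spread between replicates. The values argue against weaker siRNA action as read through carriers of this word, which was chosen as the lowest in these same data. They do not exclude it, since COL6A3 itself recovered by 39.7%, and saturation of seed repression was not tested. The median recovery over the 128 words was 16.9%. However, 5 of them recovered by 51.5% to 79.9%, with 81.5% to 88.6% of their carriers in genes with Alu words. Outside those genes carriers of the 5 words shifted in the same directions. With the siRNA the shifts were -0.12 to -0.038 (SE over genes 0.035 to 0.043). With endotrophin against siRNA alone they were 0.024 to 0.045 (SE 0.024 to 0.029), too imprecise to tell how far these carriers recovered. GC content and length do not account for the pattern, since removing their trend over 14823 genes kept at least 104% of each list's median, and nor does direct repression through the 2 seed-match words, since members with neither word kept at least 96.4%. A growth response to endotrophin stays open, which these data neither exclude nor establish. The partial return of COL6A3 mRNA and a difference in culture density or timing between the dishes stay open too, and neither was tested.

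Changes over 2-fold were mostly falls in resistant against sensitive cells and mostly rises with the COL6A3 siRNA, which both involve the resistant control. Missed low-level genes in those libraries would give this, and among genes with a mean of at least 500 counts they would leave no excess. There the larger direction still held 73.8% (95% exact binomial interval 68.1% to 79.1%) and 70.3% (64.5% to 75.7%) of calls, which argues against it at that level. For genes with a mean under 500 counts (70.4% and 80.2%) it stays open on the numbers of genes detected. The resistant control library with the fewest detected 15314, which is 13 more than the 15301 of the lowest library of the other groups. Its replicate detected 16041. A state of the resistant control cells that both comparisons share is the other explanation left, untested.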
